A study of Mus musculus with 20 samples.

How the data were processed

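Bulk RNA sequencing was done on microglia from cortex and brainstem of 10 mice, giving 20 libraries, 1 per region and mouse. Per the labels' protocols, the V600E form of Braf was activated by Cx3cr1-CreER with 1 injection of 37.5 mg per kg 4-hydroxytamoxifen into pregnant females at embryonic day 9.5. RNA was amplified with the SMART-Seq v4 kit over 12 cycles, libraries were made with the KAPA Hyper Prep kit over 8 cycles, and reads were paired-end on a NovaSeq. Per the labels, 47% to 85% of bases were mRNA and ribosomal reads averaged 0.4%. How the cells were sorted or purified was not given in the sources used here.

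The authors deposited 1 table of raw counts per gene, with no normalization. FastQC, Subread and edgeR and the mouse build mm10 were named, per the submitters' processing notes, without versions or roles. The annotation, the strand setting and the treatment of multi-mapping reads were not given in the sources used here. Genes that overlap, antisense genes and near-identical copies can therefore share reads. Of 55487 gene identifiers, 55394 were matched to symbols with the GENCODE M21 annotation of GRCm38. The 93 unnamed identifiers held 0.001% of the counts, stayed in the counts under their identifiers and were left out of the named genes. Deposited counts summed to 9.4e6 to 21.2e6 per library. A count of 0 allows up to 3 counts, which is 0.142 CPM in the deepest library and 0.319 CPM in the shallowest. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

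Libraries were grouped by region, genotype and stage as their sample records give them, with control and mutant mice numbering 3 and 3 at 2 months and 2 and 2 at end-stage. For 5 of the 6 mice at 2 months the mouse number in the title differed from the number in the description of the same record, and the description names the count column. The first reading took region and genotype from the record. Mice are named by the number in the title under both readings. An alternative reading took the genotype of the title that carries the column's mouse number, which changed the genotype of 4 of the 6 mice. It was fixed before the data were examined for genes in the 8 comparisons that include 2-month mice. Its use in the 4 end-stage comparisons, which it reaches only through the shared spread, and for all gene lists was added after the data were seen. Taking that reading as a result of its own, with its own alternatives, was decided after the data were seen, as was leaving out those 4 mice.

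Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 16595. TMM factors were used, 1 quasi-likelihood model was fitted over all 8 groups and 20 libraries, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The 12 comparisons were genotype in each region and stage, genotype by region at each stage, genotype by stage in each region, region in controls at each stage, and stage in controls in each region. Standard errors were taken from the log2 difference and the F statistic. CPM values used the TMM-scaled library sizes, and their errors are standard deviations over mice. Adjusted p-values in the text come from these tests unless another tool is named. Each mouse was 1 animal, so its 2 libraries share an animal.

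Gene lists were fixed before the data were examined: homeostatic microglia, disease-associated microglia, ERK pathway output, interferon response, cytokines and chemokines, cell cycle, complement, antigen presentation, lysosome, lipid and cholesterol handling, glycolysis, senescence-linked genes, dissociation-induced early genes, and markers of other cells and tissues. These markers were of border-associated macrophages, monocytes, neutrophils, T and NK cells, B and plasma cells, astrocytes, oligodendrocytes and their precursors, neurons, endothelial cells and pericytes, cortex tissue, brainstem tissue and sex. The cortex tissue list was not tested as a list and is used here only as a sum per library. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. Counts of list members that passed were made over all genes and adjusted over the list alone. Medians of lists were also computed with genes at 0 counts in a whole group set to their bound at 3 counts over that group. Few genes were measured for T and NK cells (2), brainstem tissue (2), B and plasma cells (3), neutrophils (4) and oligodendrocyte precursors (5).

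Named genes were taken by a rule fixed before the data were examined. It took, among genes that passed with a mean log2 CPM of at least 1 and no overlap of the groups, the 8 with the largest rise and the 8 with the largest fall (5 and 5 outside the genotype comparisons). It left out predicted genes, Riken clones and pseudogenes. It also took up to 4 members of each list by p (2 outside the genotype comparisons, or where none passed), and 20 markers given in every genotype comparison. Genes outside the rule are said to be so.

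Alternatives were DESeq2 1.42.0, limma-voom with a correlation for mouse, RLE size factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, an added threshold of 1 on the absolute log2 difference, only the compared groups in the model, the mouse-number reading, each mouse left out in turn, and mouse as a replicate block. Where leaving out a mouse left 1 library in a group, that library was assumed to vary like the other groups. The replicate number is the mouse, so region comparisons are paired by animal. After group means were removed, libraries of the same mouse correlated at 0.10 to 0.34 (median 0.26), and 20 of 20 libraries correlated best with the other library of their own mouse. No 2 libraries held identical values.

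The procedure was tested on simulated counts with the real means and library sizes, in which 200 genes were changed. Their spread was that of the fit grouped by the record, so the shares called hold for that grouping. For genotype in cortex at 2 months, on 15915 genes, 20.9% of genes changed 2-fold, 68.7% of those changed 4-fold and 90.9% of those changed 16-fold were called, with 3 unchanged genes called. For genotype in cortex at end-stage, on 15947 genes, the shares were 13.4%, 64.2% and 83.3%, with 7 unchanged genes called. For genotype in brainstem they were 28.4%, 68.7% and 87.9% at 2 months and 11.9%, 62.7% and 87.9% at end-stage. For genotype by region they were 10.4%, 55.2% and 80.3% at 2 months and 0%, 25.4% and 74.2% at end-stage. For genotype by stage they were 0%, 47.8% and 71.2% in cortex and 3.0%, 44.8% and 75.8% in brainstem. For region in controls they were 28.4%, 64.2% and 92.4% at 2 months and 11.9%, 47.8% and 86.4% at end-stage. For stage in controls they were 14.9%, 61.2% and 90.9% in cortex and 13.4%, 70.1% and 89.4% in brainstem. The wrong direction was called for 0 genes, and 2 to 7 unchanged genes were called per comparison. The list that was raised was called in all 12 simulated comparisons, and 1 list that was not raised was called in stage in controls in cortex and 0 in the other 11. Simulated genes varied independently of each other, unlike real ones. Figures were drawn with matplotlib 3.10.9.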

Results

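Microglia, the resident macrophages of the brain, were profiled from cortex and brainstem of mice in which BRAF V600E, a constitutively active kinase of the ERK cascade, had been switched on in embryonic microglial progenitors. The series asked how these cells differ from control microglia in each region, at 2 months and at the stage the labels call end-stage, in a model of neurodegeneration in histiocytosis. Each region held 3 control and 3 mutant libraries at 2 months and 2 control and 2 mutant libraries at end-stage. Library totals of counts at end-stage were 9.4e6 and 14.3e6 in cortex controls, 17.3e6 and 18.5e6 in cortex mutants, 14.6e6 and 19.4e6 in brainstem controls, and 15.6e6 and 18e6 in brainstem mutants. At 2 months they ranged from 16.9e6 to 21e6 in cortex controls, 14.8e6 to 19.2e6 in cortex mutants, 14.2e6 to 21.2e6 in brainstem controls, and 12.9e6 to 19e6 in brainstem mutants.

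Cx3cr1, the fractalkine receptor gene into which the Cre was inserted, stood at 4400 and 5780 CPM in the libraries of the 1 mouse labelled wild type at that locus, end-stage control mouse M1375. It ranged from 998 to 2850 CPM in the 18 libraries labelled heterozygous. Mouse M1375 carried the Braf allele without Cre, and the other end-stage control, mouse M1521, carried Cre without the Braf allele. Braf itself did not differ at end-stage in cortex (15.8 ± 2.98 against 10.8 ± 6.80 CPM, SD, n = 2 each, adjusted p = 0.709), and gene counts do not read the V600E change. Etv4, a transcription factor induced by ERK signalling, stood at 8.07 to 12.6 CPM in the 4 end-stage mutant libraries and at 0 to 1.44 CPM in the 4 end-stage controls. Its test did not pass in cortex (log2 difference 3.42 ± 2.04 SE, adjusted p = 0.456) or brainstem (4.14 ± 2.09, adjusted p = 0.713).

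The labels of the 2-month mice conflicted. For 5 of these 6 mice the number in the title differed from the number in the description, which names the count column. Reading genotype through that number instead of the record changed it for 4 mice. The column names also hold a running sample number. Sorted by it, the mouse numbers of the columns follow the order of the record titles for all 6 mice. The descriptions instead run in ascending mouse number. This order, looked at after the data were seen, argues for the mouse-number reading but is not proof of it. Comparisons at 2 months are given under both readings, with 3 against 3 mice in each. The mouse-number reading was planned for genes in comparisons that include 2-month mice. Its values for end-stage comparisons, which it reaches only through the shared spread, and for gene lists were added after the data were seen.

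The region labels were also checked. Transcripts of brainstem tissue, mostly Hox genes that pattern the hindbrain, summed to 1.93 ± 0.602 CPM in cortex-labelled libraries and 0.732 ± 0.362 CPM in brainstem-labelled libraries (SD, n = 10 each). They were higher in the cortex-labelled library in 10 of 10 mice (exact 2-sided sign-flip permutation test p = 0.00195, the smallest that 10 pairs allow, and 0.00521 after Benjamini-Hochberg adjustment over 8 tests). Hoxb5 had 101 counts over the cortex-labelled libraries and 2 over the brainstem-labelled ones. Transcripts of cortex tissue did not differ (0.632 ± 0.440 against 0.729 ± 0.563 CPM, exact p = 0.719). Because the brainstem transcripts went against the label, libraries are called cortex-labelled and brainstem-labelled throughout.

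**Figure D1:**
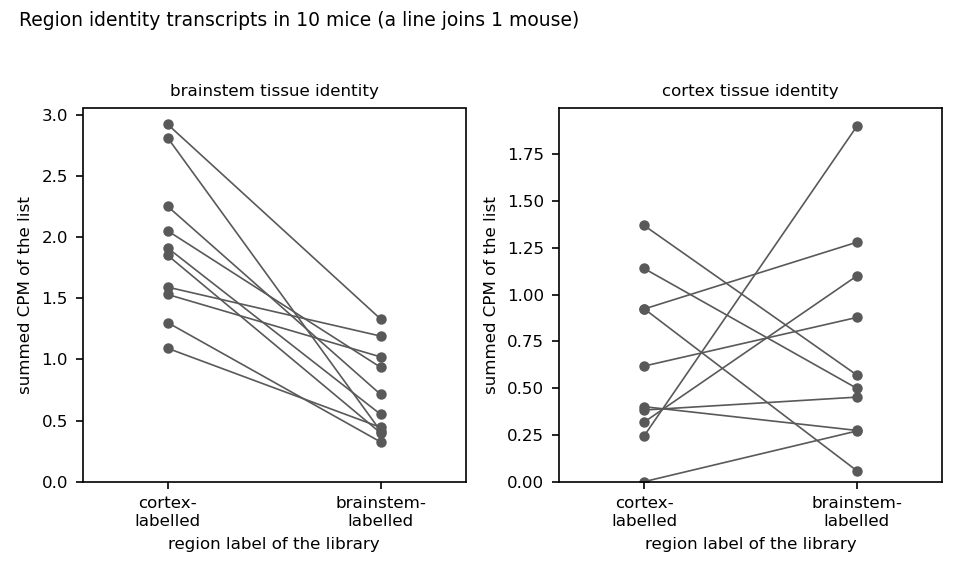
Summed CPM of brainstem tissue transcripts (left) and cortex tissue transcripts (right) by the region label of the library, where each line joins the 2 libraries of 1 mouse. Brainstem transcripts lay higher in the cortex-labelled library in 10 of 10 mice, and cortex transcripts in 4 of 10.

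At end-stage, cortex-labelled mutant microglia carried far more transcript of Apoe, Lpl, Abcg1 and a few other lipid-handling genes than controls, and less of the homeostatic genes Fcrls, Selplg and Sparc. Apoe, a lipid carrier, reached 98900 ± 5050 CPM in mutants against 829 ± 235 CPM in controls (SD, n = 2 each, log2 difference 6.90 ± 1.0 SE, adjusted p = 0.00334). Lpl, a lipase, rose from 16.8 ± 9.07 to 335 ± 166 CPM (adjusted p = 0.0177), and Fabp5, a fatty acid carrier, from 2.36 ± 0.636 to 31.0 ± 4.86 CPM (adjusted p = 0.0093). Gpnmb, a glycoprotein of lipid-laden macrophages, had 0 counts in controls and 44.0 ± 32.1 CPM in mutants, at least 353-fold higher at 3 counts over the control group (adjusted p = 0.0376). Igf1, a growth factor, also rose. In the disease-associated list, 6 of 26 measured members rose and 0 fell over all genes, and 17 rose adjusted over the list alone, with a median log2 difference of 2.23. The camera test gave an adjusted p of 3.70e-14 for this list, and an adjusted p = 0.0528 with an estimated correlation. Spp1 (6.02 ± 2.33, adjusted p = 0.246) and Itgax (3.83 ± 1.16, adjusted p = 0.14) did not pass, though by mouse number both did (0.0270 and 0.00928), and Trem2, the lipid-sensing receptor, stood at −0.19 ± 0.25.

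The sterol transporters Abcg1 and Abca1 rose with them. Abcg1 went from 24.2 ± 1.04 to 169 ± 10.5 CPM (log2 difference 2.80 ± 0.29, adjusted p = 0.000434) and Abca1 from 65.7 ± 20.5 to 355 ± 36.2 CPM (adjusted p = 0.0169). With the apolipoprotein Apoc1 they made 3 of 19 members of the lipid and cholesterol list that rose, 7 adjusted over the list alone (median 0.73, camera adjusted p = 3.71e-07, adjusted p = 0.146 with an estimated correlation). Gla, a lysosomal galactosidase, was the 1 of 24 lysosome genes that rose (median 0.28, adjusted p = 0.0164, and 0.565 with an estimated correlation). Among the largest rises were Fn1 and Postn, matrix proteins, Dgat2, a triglyceride synthase, Sh3pxd2b, Kcnn4 and Egr2. Postn rose from 1.15 ± 0.122 to 52.4 ± 22.6 CPM (adjusted p = 0.00303). Fn1 (487 ± 532 CPM in mutants) differed widely between the 2 mutant mice. Cspg4, in the oligodendrocyte precursor list, rose from 0.688 ± 0.673 to 62.4 ± 35.9 CPM (adjusted p = 0.0268), while that list had a median of −4.36 (−1.94 with genes at 0 set to their bound, mean −1.28, camera adjusted p = 0.961).

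In the same libraries 3 homeostatic genes fell. Fcrls, an Fc receptor-like microglial marker, fell from 2350 ± 282 to 643 ± 5.84 CPM (log2 difference −1.87 ± 0.41, adjusted p = 0.0353). Selplg, a selectin ligand, fell by 1.13 ± 0.23 and Sparc, a matrix protein, fell by 0.97 ± 0.19 on the log2 scale (adjusted p = 0.0206 each). These were the 3 of 21 members of the homeostatic list that fell over all genes; 14 fell adjusted over the list alone (median −0.78, camera adjusted p = 7.59e-12, adjusted p = 0.0528 with an estimated correlation). P2ry12, a purinergic receptor (−1.38 ± 0.40, adjusted p = 0.127), Tmem119 (−0.56 ± 0.28, adjusted p = 0.362), Sall1 (−0.78 ± 0.26, adjusted p = 0.177) and Cx3cr1 (−1.15 ± 0.44, adjusted p = 0.240) did not pass. Cx3cr1 is confounded with its own locus, wild type in control M1375 (4400 CPM). Heterozygous control M1521 stood at 2160 CPM and the heterozygous mutants at 1460 and 1500 CPM. When the 2-month mice in the model were read by mouse number, P2ry12 (0.00448) and Sall1 (0.0393) passed, as did P2ry13 and Gpr34, and the homeostatic and disease-associated lists held with an estimated correlation (0.00472 and 0.0191). Enpp5, Mmp28, Myo18b and Ptger3 had 0 counts in both mutant libraries and stood at 13.4 ± 7.17, 9.04 ± 3.98, 4.41 ± 1.89 and 3.15 ± 1.84 CPM in controls, at least 150-, 102-, 49.6- and 35.4-fold lower. Sema4b, a semaphorin, fell from 18.9 ± 3.39 to 0.164 ± 0.231 CPM, and Prkcq (79.2-fold), Snph (60.3-fold) and Gpr165 (59-fold) also fell. Il6, an inflammatory cytokine, fell from 20 ± 0.814 to 3.19 ± 2.12 CPM (adjusted p = 0.0263).

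Early-response genes went both ways: Dusp1, a MAP kinase phosphatase, rose from 8.72 ± 0.0537 to 59 ± 9.80 CPM (adjusted p = 0.000434), and Jun, a subunit of AP-1, fell from 158 ± 35.6 to 63.1 ± 0.450 CPM (adjusted p = 0.00442). Their list of 14 dissociation-induced genes had a median of 0.39 (camera adjusted p = 0.0358, and 0.252 with an estimated correlation). Camera also placed the senescence-linked list (median 1.90, adjusted p = 0.000464), the interferon list (1.79, 0.00865), cytokines and chemokines (2.00, 0.0361) and complement (0.38, 0.0358) higher. With an estimated correlation their adjusted p-values were 0.146, 0.740, 0.740 and 0.252, and 0 members of these 4 lists rose over all genes. By mouse number, 2 senescence-linked genes (Cdkn2a and Plaur), 6 cytokines and chemokines (Il1b and Ccl4 among them), 2 complement genes (C3 and C4b) and 0 interferon genes rose. Senescence-linked members that rose numbered 5 of 13 adjusted over the list alone. The lists of ERK output (median 0.41, adjusted p = 0.283), cell cycle (−0.19, 0.696), antigen presentation (0.48, 0.260) and glycolysis (−0.02, 0.961) did not pass.

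Markers of other cells went both ways within their lists. Neurons (11 measured genes, median −2.04, −1.57 at the bound, camera adjusted p = 0.0162) and T and NK cells (2 measured genes, −2.87, 0.0216) were lower. So were B and plasma cells (3 measured genes, −1.51, mean −0.38, 0.0250), where Ighm, the IgM heavy chain, fell. With an estimated correlation these adjusted p-values were 0.252, 0.146 and 0.146. Border-associated macrophages (0.35, 0.961), monocytes (0.21, 0.261), neutrophils (0.00, 0.961), astrocytes (0.00, 0.861), oligodendrocytes (−1.33, 0.128) and endothelial cells and pericytes (0.06, 0.720) did not pass. Nor did brainstem tissue (−3.84, −2.02 at the bound, 0.231) or the sex markers (0.00, 0.961). The astrocyte gene Gfap stood at 6.95 ± 6.28 CPM in mutants and 0.193 ± 0.176 CPM in controls (adjusted p = 0.0568). Flt1 (5.98 ± 2.15, 0.210), Siglec1 (4.53 ± 2.29, 0.373) and Ms4a6c (2.49 ± 0.59, 0.0553), markers of endothelium, border macrophages and monocytes, stood high without passing. Under the mouse-number reading Gfap (0.0153), Flt1 (0.0417), Kdr (0.00825) and Ms4a6c (0.00151) rose, and Pecam1 (0.0264), Cd79b (0.00143) and Klrd1 (0.0324) fell.

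In all, the edgeR quasi-likelihood test called 171 of 16595 genes in end-stage cortex-labelled libraries, 63 higher and 108 lower. The count fell to 10 without control mouse M1375, 22 without mutant M1376, 18 without control M1521 and 26 without mutant M1524. It was 694 with DESeq2, 451 with only the compared groups, 666 when 2-month genotype was read by mouse number, and 1026 without a low-count filter. Of 31 named genes that passed, 3, 5, 5 and 7 remained called without mice M1375, M1376, M1521 and M1524, and Abcg1, Dusp1 and Enpp5 were called in each case, while Apoe was lost without mouse M1375 (adjusted p = 0.0896) or M1521 (0.0542). The camera calls of the homeostatic, disease-associated, lipid and senescence-linked lists held without each mouse. Without mouse M1375 the interferon, complement, lysosome and B and plasma cell calls (adjusted p = 0.0721 each) and the cytokine call (0.337) were lost. Without M1524 the interferon (0.436), complement (0.191), lysosome (0.188), B and plasma cell (0.173), dissociation (0.0642) and neuron (0.0647) calls were lost, and without M1521 the complement (0.071), dissociation (0.312) and neuron (0.366) calls. The T and NK cell call was lost without any of the 4 mice (0.124 to 0.971).

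**Figure D2:**
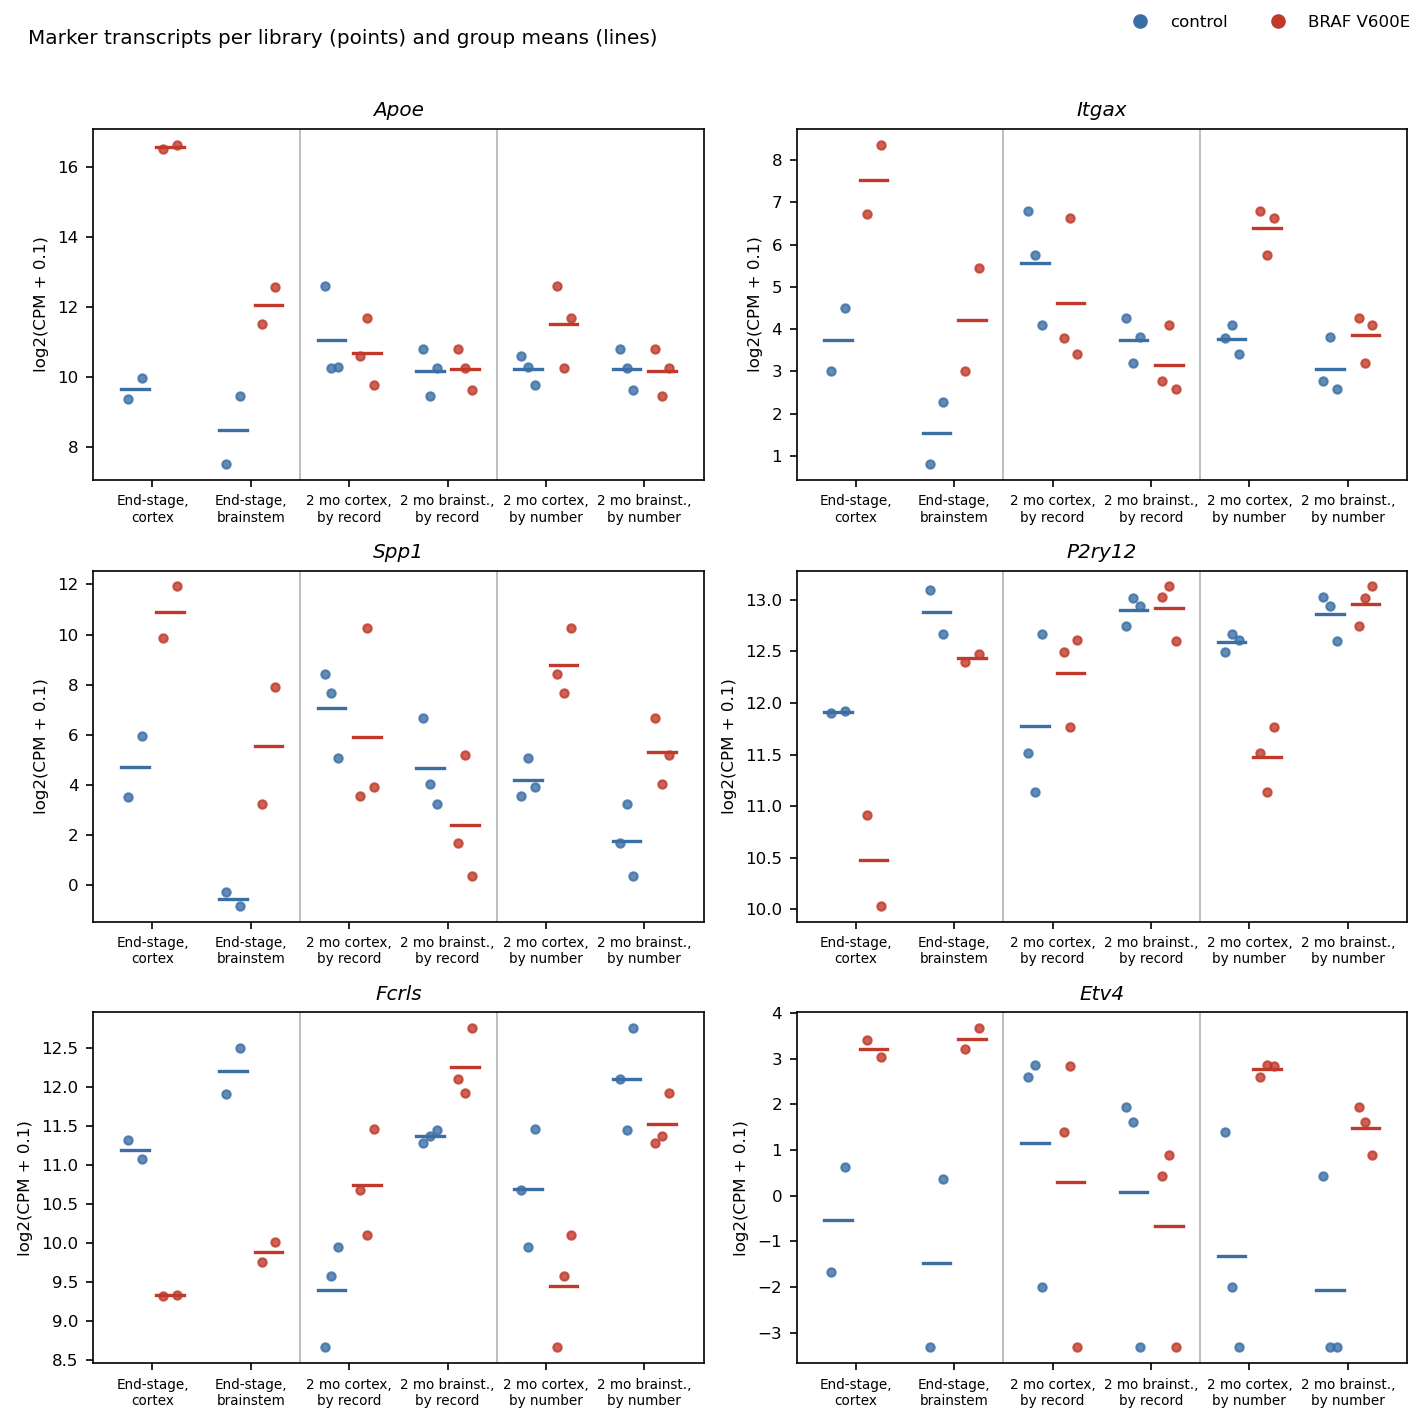
CPM of 6 marker genes on a log2 scale with 0.1 added, where points are libraries, lines are group means of the logged values, blue is control and red is BRAF V600E. At end-stage, Apoe stood at 98900 CPM in cortex-labelled mutants and 829 CPM in controls (means, n = 2 each), and the 2-month panels show the same 12 libraries under both readings of the labels.

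In end-stage brainstem-labelled libraries, 1 gene passed. Jun fell from 163 ± 0.0397 to 49.8 ± 4.36 CPM in mutants (SD, n = 2 each, log2 difference −1.71 ± 0.20, adjusted p = 0.00275). Apoe stood at 4520 ± 2230 CPM in mutants and 442 ± 368 CPM in controls (3.35 ± 0.85, adjusted p = 0.446), Lpl at 21.5 ± 3.59 and 5.18 ± 2.55 CPM, and Spp1 at 123 ± 161 and 0.601 ± 0.190 CPM; none of these passed. Camera placed the interferon list (median 3.28, adjusted p = 1.55e-10), disease-associated genes (0.46, 0.00259), lipid genes (0.68, 0.00799) and oligodendrocyte precursors (3.16, 2.87 at the bound, 0.0122) higher and homeostatic genes lower (−0.46, 0.000143). With an estimated correlation the adjusted p-values were 0.612, 0.612, 0.612, 0.500 and 0.500, and 0 members of these lists passed over all genes. The disease-associated call was lost without mouse M1375 (adjusted p = 0.820) or M1524 (0.388), the homeostatic call without M1376 (0.125), the lipid call without M1375 (0.241) or M1524 (0.111), and the precursor call without M1375 (0.223) or M1376 (0.0823). The count of 1 became 0 without mutant M1376 or M1524, 2 without control M1521, and 4 with only the compared groups, where Jun was lost (adjusted p = 0.123) and the 4 were other genes, all higher. It was 25 under the mouse-number reading, 70 with DESeq2 and 436 without a low-count filter.

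Whether the genotype difference itself differed between regions at end-stage was tested as an interaction. The edgeR quasi-likelihood test called 0 genes, with 659 at an unadjusted p under 0.05, 43 by DESeq2, 1 by limma-voom, 14 under the mouse-number reading and 162 without a low-count filter. With mouse as a replicate block it called 5. By camera, the disease-associated list differed less between genotypes in brainstem-labelled than in cortex-labelled libraries (median difference −0.72, adjusted p = 1.19e-07, and 0.201 with an estimated correlation), and the homeostatic list fell less (0.37, 0.000566, and 0.223). Interferon (1.55, 0.0104), neuron (2.57, 0.00256), oligodendrocyte precursor (6.88, 0.0170) and T and NK cell lists (2.70, 0.00378) went the other way, with the higher difference in brainstem-labelled libraries. The T and NK cell list held 2 measured genes. The precursor list held 5, and its 6.88 was not computed with genes at 0 set to their bound. At the bound its genotype medians were −1.94 in cortex-labelled and 2.87 in brainstem-labelled libraries. Senescence-linked (−1.38, 0.00190), dissociation (−0.52, 0.000362), lipid (−0.17, 0.0104) and lysosome lists (−0.17, 0.0170) had the lower difference there. These adjusted p-values were 0.159 to 0.787 with an estimated correlation. Only the disease-associated and homeostatic calls held without each mouse, and the replicate block ended the precursor call (0.0546).

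At 2 months by the sample record, mutants and controls differed in 1 gene in each region, with 694 genes in cortex-labelled and 603 in brainstem-labelled libraries at an unadjusted p under 0.05. The gene was Prkd1, a serine/threonine kinase of the protein kinase D family (ENSMUSG00000002688.8, chromosome 12, 50341231 to 50649098, GRCm38), which lies outside the rule for named genes and was named after its values were seen. It stood at 4.36 to 15.1 CPM in the 3 cortex-labelled and 12.1 to 21.2 CPM in the 3 brainstem-labelled libraries of record controls. In record mutants it had 0 counts in 5 libraries and 1 count in 1 (adjusted p = 0.0239 in cortex-labelled and 0.0194 in brainstem-labelled libraries). All 8 end-stage libraries had 0 counts of Prkd1, and 0 of 14 tested genes within 3 Mb of it passed. P2ry12 (0.41 ± 0.32 and 0.03 ± 0.32 in cortex-labelled and brainstem-labelled libraries), Apoe (−0.60 ± 0.63 and 0.03 ± 0.63) and Etv4 (−0.46 ± 1.49 and −1.16 ± 1.57) did not pass.

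Camera placed several lists lower in record mutants at 2 months. In cortex-labelled libraries these were interferon response (median −0.84, adjusted p = 5.39e-05), cytokines and chemokines (−0.85, 3.81e-05), cell cycle (−0.71, 5.05e-06) and antigen presentation (−0.65, 2.23e-05), with homeostatic genes higher (0.24, 0.000379). With an estimated correlation these adjusted p-values were 0.618 to 0.621. In brainstem-labelled libraries, border-associated macrophages (−1.57, 0.000136), ERK output (−0.43, 0.00378), cytokines (−0.78, 0.00737), cell cycle (−0.52, 0.0372) and senescence-linked genes (−0.67, 0.0439) were lower, and B and plasma cells were higher (0.63, 0.0372). With an estimated correlation these adjusted p-values were 0.476 to 0.903. Prkd1 was lost without any 1 of the 6 mice. Leaving out a mouse gave 0 genes in each region, except that without M2633 the test called 1 other gene, higher in mutants, in each. Among cortex-labelled lists, the homeostatic call was lost without M2617 (adjusted p = 0.0548) or M2629 (0.0511), the interferon call without M2617, M2618, M2621 or M2629 (0.0654 to 0.185), the cytokine call without M2629 (0.0939) and the cell-cycle call without M2617 (0.0654). Among brainstem-labelled lists only the border macrophage call held without each mouse. DESeq2 called 5 genes in cortex-labelled and 12 in brainstem-labelled libraries, limma-voom 3 and 1, only the compared groups 0 and 1, and no low-count filter 149 and 154.

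Read by mouse number, the same 12 libraries gave a different picture at 2 months. Cortex-labelled libraries of the 3 mice so read as mutant held far more interferon-response, cell-cycle and cytokine transcripts than those of the 3 so read as control. All 20 measured interferon-response genes rose (median 4.43, camera adjusted p = 6.33e-43, 0.0245 with an estimated correlation). Usp18, an interferon-induced protease, stood at 442 ± 64.9 against 15 ± 3.73 CPM (SD, n = 3 each), Bst2, an interferon-induced membrane protein, at 454 ± 129 against 74.6 ± 13.5 CPM, and Isg15 at 102 ± 35.6 against 5.68 ± 2.56 CPM. Of 25 cell-cycle genes 18 rose (median 3.70, adjusted p = 2.81e-29, 0.0118 with an estimated correlation), among them Cdk1, the mitotic kinase, at 42.8 ± 4.92 against 6.99 ± 2.69 CPM. Of 19 cytokines and chemokines 12 rose (median 2.02, 1.18e-12, 0.0429), including Il1b at 49.8 ± 10.1 against 3.13 ± 0.911 CPM and Ccl2 at 336 ± 267 against 7.60 ± 4.84 CPM. Of 17 antigen presentation genes 7 rose (median 0.98, 4.18e-09, 0.0429), including the class I gene H2-D1 at 11100 ± 4160 against 1580 ± 514 CPM.

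Parts of the disease-associated, lipid and homeostatic lists also differed under this reading. Of 26 disease-associated genes 10 rose over all genes and 16 adjusted over the list alone (median 0.79, adjusted p = 3.56e-08, 0.0759 with an estimated correlation). They included Axl, a receptor for dying cells, at 781 ± 116 against 27.3 ± 14 CPM, Cst7, a cystatin, at 47.3 ± 4.72 against 5.43 ± 0.395 CPM, Itgax at 88.0 ± 29.8 against 13.8 ± 3.28 CPM, and Spp1, osteopontin, at 588 ± 550 against 20.2 ± 11.7 CPM. Apoe stood at 3560 ± 2490 against 1220 ± 343 CPM and did not pass (adjusted p = 0.104). Of 21 homeostatic genes 5 fell (median −0.30, adjusted p = 1.91e-06, 0.0385 with an estimated correlation). P2ry12 stood at 2890 ± 616 against 6180 ± 381 CPM and Gpr34, a lysophospholipid receptor, at 1020 ± 207 against 2700 ± 187 CPM. Sema4b fell as well, from 20.3 ± 6.03 to 2.42 ± 1.0 CPM. Lipid and cholesterol genes (6 of 19 higher, median 1.0, 0.0429 with an estimated correlation) included Cd36, a fatty acid scavenger, and Sqle of sterol synthesis. Senescence-linked genes (3 of 13 higher, median 1.51, 0.0429) included the cell-cycle inhibitor Cdkn1a. Etv4 stood at 6.72 ± 0.688 against 0.888 ± 1.41 CPM and did not pass (adjusted p = 0.208), and 1 of 16 ERK output genes, Myc, rose (median 0.77, 0.00915, 0.191). Monocyte genes Plac8, Ms4a4c and Ms4a6c rose (median 2.44, 1.75 at the bound, 0.00121, 0.102), and of the border macrophage genes Siglec1 rose and Stab1 fell (median −1.95, adjusted p = 0.0837). Of the dissociation-induced genes, which respond to handling, Egr1, Ier2 and Nfkbiz rose and Jund fell (median 0.31, 0.0499, 0.292), and the endothelial genes Kdr and Flt1 rose (median 0.92, 0.00810, 0.0429).

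The edgeR quasi-likelihood test called 904 genes under this reading, 604 higher and 300 lower, in cortex-labelled libraries, and 6 in brainstem-labelled libraries. The count was 462 without mouse M2621 and 585 without mouse M2633. Mice are named by their title number, and M2621 and M2633 were both read as control under this reading. The count was 571 with an added threshold of 1 on the log2 difference, 1562 with DESeq2 and 1551 without a low-count filter. In brainstem-labelled libraries Pear1, Mmd and Jup rose and Pmp22, a myelin protein, Atf3, a stress transcription factor, and Gpr160 fell. Pear1 stood at 63.6 ± 5.52 against 17.1 ± 1.61 CPM and Pmp22 at 289 ± 49.4 against 853 ± 37.2 CPM. All 20 interferon genes rose there adjusted over the list alone, 0 over all genes (median 2.77, adjusted p = 1.21e-28, 0.0676 with an estimated correlation), and 8 of 16 ERK output genes rose adjusted over the list alone (median 0.68, 6.22e-09, 0.0542). The count of 6 became 1 without mouse M2617, 0 without M2621, 2 without M2624, 11 without M2633, 11 with limma-voom, 2 with only the compared groups, 198 with DESeq2 and 499 without a low-count filter.

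**Figure D3:**
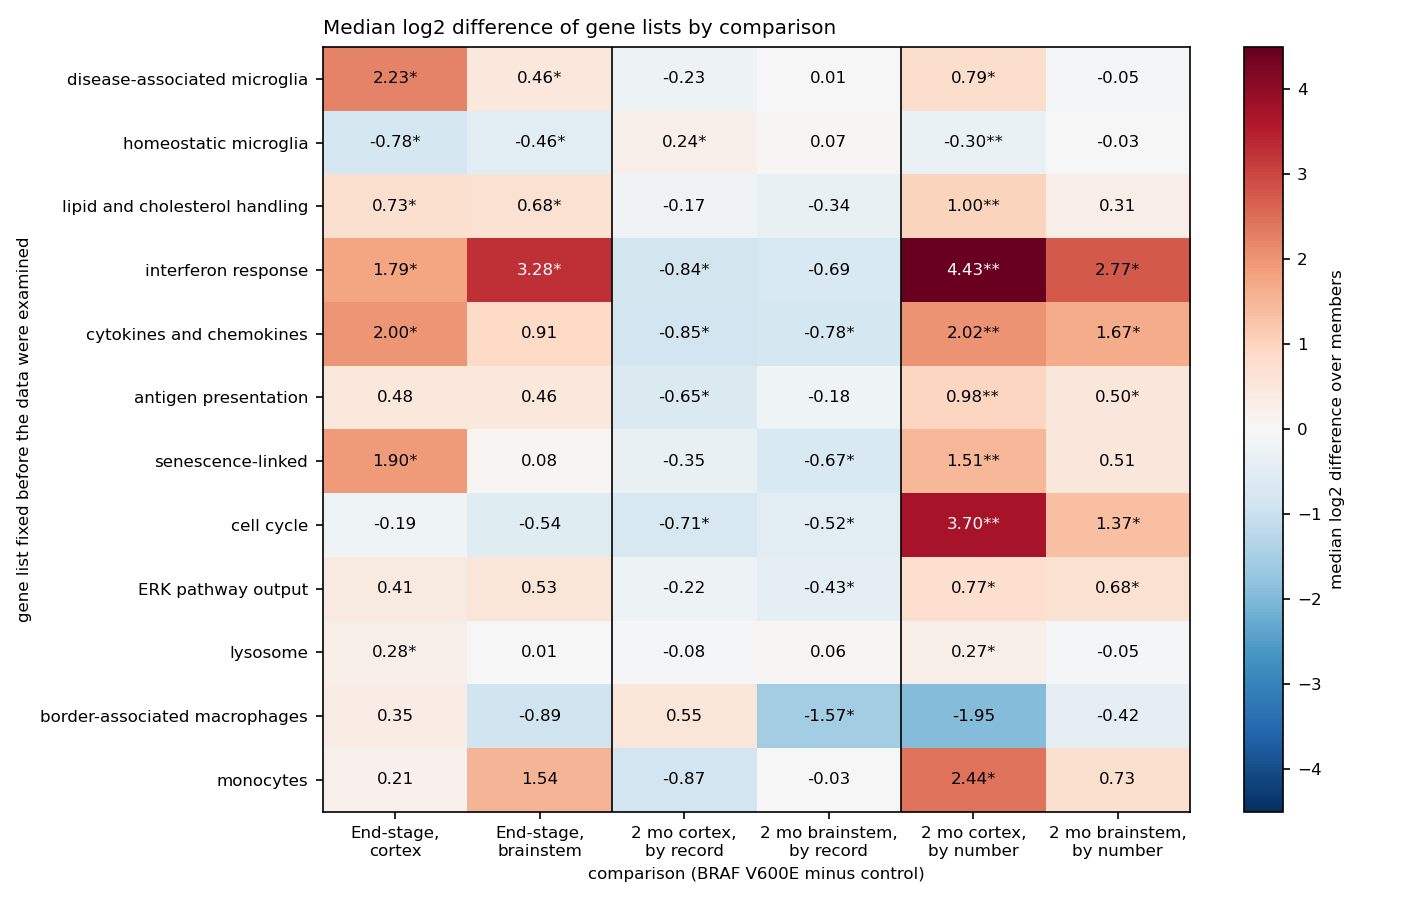
Median log2 difference (mutant minus control) over the members of 12 gene lists, in cortex-labelled and brainstem-labelled libraries at end-stage and at 2 months under both readings. One star marks a camera adjusted p under 0.05, and a pair of stars marks that the call also held with an estimated correlation.

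By the record, the genotype difference at 2 months did not differ between regions in any gene that passed. The edgeR quasi-likelihood test called 0 genes, with 552 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom, 0 with mouse as a replicate block and 33 without a low-count filter. Camera placed border-associated macrophage genes lower in this difference (median −3.35, adjusted p = 2.28e-05, and 0.854 with an estimated correlation). By mouse number 4 genes were called, and camera turned the direction of the border macrophage list (adjusted p = 0.0351). Camera also called the lysosome list by the record. That call was lost without M2617 (0.495), M2618 (0.215), M2621 (0.254) or M2629 (0.355). The lysosome list turned direction by mouse number (camera adjusted p = 2.42e-07).

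Genotype differences were also compared between stages. By the record, in cortex-labelled libraries Apoe differed between genotypes by 7.50 ± 1.14 more on the log2 scale at end-stage than at 2 months (adjusted p = 0.0082), Bambi, a TGF-beta pseudoreceptor, by 4.81 ± 0.54 (0.00173), and Dusp1 by 3.18 ± 0.38 (0.00183). Fcrls moved by −3.23 ± 0.53 (0.0113) and Jun by −1.75 ± 0.25 (0.0082). The disease-associated list differed upward (3 of 26 higher, 9 adjusted over the list alone, median 2.65, camera adjusted p = 2.90e-14, 0.0483 with an estimated correlation) and the homeostatic list downward (1 of 21 lower, 12 adjusted over the list alone, median −1.08, 1.90e-13, 0.0483). In brainstem-labelled libraries Fcrls (−3.28 ± 0.53, 0.0469) and Jun (−1.86 ± 0.25, 0.0220) passed among named genes. The edgeR quasi-likelihood test called 75 genes in cortex-labelled and 4 in brainstem-labelled libraries.

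These stage differences depended in part on the 2-month labels. By mouse number 44 and 1 genes were called, and 8 of the 16 named genes in cortex-labelled libraries remained called, with Apoe at 5.35 (adjusted p = 0.0145) and Fcrls at −0.61 (0.772). The list medians by mouse number were 0.54 for disease-associated genes (camera adjusted p = 6.51e-06) and −0.41 for homeostatic genes (0.00202), and neither call held with an estimated correlation (adjusted p = 0.218 each). Interferon genes turned from 2.56 by the record (2.88e-05, 0.419 with an estimated correlation) to −2.41 (4.35e-16, 0.218), and cell-cycle genes stood at −3.59 by mouse number (2.94e-27, 0.0162). Without the 4 mice whose genotype differed between readings, 2 and 1 genes were called, but 1 mouse per genotype was then left at 2 months, too few to tell what the labels did. In cortex-labelled libraries the count of 75 became 5, 22, 16 and 7 without end-stage mice M1375, M1376, M1521 and M1524. It became 37, 28, 29, 530, 37 and 352 without 2-month mice M2617, M2618, M2621, M2624, M2629 and M2633. It was 506 with DESeq2, 36 with limma-voom, 6 with only the compared groups and 1011 without a low-count filter. In brainstem-labelled libraries it was 12 without mouse M2624, 4 without M2633, 1 without M2617 and 0 without any other mouse, 76 with DESeq2, 2 with limma-voom, 2 with only the compared groups and 507 without a low-count filter.

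Among record controls at 2 months, brainstem-labelled and cortex-labelled microglia differed in 10 genes, with Abcg1, the sterol transporter, at the smallest p. Abcg1 stood at 112 ± 14.3 CPM in brainstem-labelled and 19.2 ± 5.07 CPM in cortex-labelled libraries (SD, n = 3 each, log2 difference 2.54 ± 0.23, adjusted p = 9.74e-05), and Scd2, a fatty acid desaturase, at 99.0 ± 13.3 and 30.9 ± 7.46 CPM (0.0483). Fcrl1, Fam110a, Adcy8 and Btbd17 were also higher. Csf2ra, a subunit of the GM-CSF receptor (64.8 ± 12.3 against 236 ± 16.6 CPM, 0.0132), Neat1, a nuclear long noncoding RNA (6.15 ± 1.97 against 27.7 ± 1.26 CPM, 0.0132), Ifi30, a lysosomal thiol reductase, and B3gnt8 were lower. Adcy8 and Btbd17 lie outside the rule for named genes and were named after their values were seen. The lipid and cholesterol list did not pass (2 of 19 higher, median −0.90, camera adjusted p = 0.793). Homeostatic genes were higher as a list in brainstem-labelled libraries (0 of 21 passed, 5 adjusted over the list alone, median 0.48, camera adjusted p = 2.79e-10, 0.0498 with an estimated correlation). Oligodendrocyte genes were lower (median −2.15, 0.000312, 0.0498), as were interferon (−2.57, 6.95e-09) and cell-cycle genes (−2.68, 6.95e-09), both at 0.428 with an estimated correlation. Control mice M2618 and M2629 are read as mutant by mouse number. Under that reading interferon and cell-cycle medians rose more in cortex-labelled (4.43 and 3.70) than in brainstem-labelled mutants (2.77 and 1.37). If it holds, these interferon and cell-cycle differences cannot be told apart from genotype.

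The edgeR quasi-likelihood test called 10 genes, 6 higher and 4 lower. With mouse as a replicate block, which pairs the regions of each animal, it called 274, and camera then lost the astrocyte and border macrophage calls. Abcg1 remained called without each mouse. The count was 1 without mouse M2618 or M2629, 2 without M2633, 0 without the 4 mice whose genotype differed between readings, 24 by mouse number, 3 with only the compared groups, 22 with the stricter filter, 108 with limma-voom, 267 with DESeq2 and 734 without a filter. In end-stage controls Abcg1 alone was called, at 121 ± 8.64 CPM in brainstem-labelled and 24.2 ± 1.04 CPM in cortex-labelled libraries (SD, n = 2 each, 2.31 ± 0.28, adjusted p = 0.00576). The block raised that count from 1 to 30 and ended the camera call of the brainstem tissue list. Abcg1 was lost without mouse M1375 (adjusted p = 0.871) or M1521 (0.166) and with only the compared groups (0.0963). The count was 0 without mouse M1375, 2 without M1521, 0 with only the compared groups, 9 by mouse number, 11 with limma-voom, 105 with DESeq2 and 441 without a filter. Disease-associated genes were lower as a list in end-stage brainstem-labelled controls (median −0.63, camera adjusted p = 4.78e-05, 0.383 with an estimated correlation). The 2 measured brainstem tissue genes were lower too (median −4.23, −2.46 at the bound, camera adjusted p = 0.0353, 0.231 with an estimated correlation).

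Between stages, record controls differed in few genes. In cortex-labelled libraries Adcy8, an adenylate cyclase, Fcrl1 and the pseudogene Gpr137b-ps were higher at end-stage, Fcrl1 at 52.4 ± 13.6 (SD, n = 2) against 15.6 ± 2.59 CPM (SD, n = 3, log2 difference 1.75 ± 0.24, adjusted p = 0.0158). In brainstem-labelled libraries Gpr137b-ps was higher and Prkd1 lower (adjusted p = 0.0347 each). Adcy8, Gpr137b-ps and Prkd1 lie outside the rule for named genes. By camera, interferon (median −2.55, adjusted p = 7.73e-06) and cell-cycle genes (−2.41, 1.32e-07) were lower in end-stage cortex-labelled controls, and interferon genes (−1.90, 0.000571) and ERK output (−0.94, 3.33e-05) in brainstem-labelled ones. With an estimated correlation these adjusted p-values were 0.353 to 0.562. By mouse number the cortex-labelled medians turned to 1.16 for interferon (6.66e-07) and 0.68 for cell cycle (0.0209), and the brainstem-labelled ones stood at 0.39 for interferon (0.333) and −0.25 for ERK output (0.615). The brainstem-labelled interferon call was also lost without M1375 (0.374) or M2618 (0.627). End-stage controls were all female and 1 of 3 record controls at 2 months was male. End-stage control M1375 carried the Braf allele without Cre, while every 2-month control was labelled with Cre and without the Braf allele. Stage in controls cannot be told apart from these differences. The edgeR quasi-likelihood test called 3 genes in cortex-labelled and 2 in brainstem-labelled libraries, and by mouse number 0 in each, with 1432 and 1367 at an unadjusted p under 0.05. In cortex-labelled libraries the count was 0 without mouse M1375 or M2629, 0 with only the compared groups, 1 with limma-voom and 41 with DESeq2. In brainstem-labelled libraries it was 0 without M1375, M2618 or M2629, 1 without M1521 or M2633, 1 with only the compared groups, 0 with limma-voom, 32 with DESeq2 and 4 without the 4 mice whose genotype differed. Without a low-count filter the counts were 473 and 248.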

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

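The genotype difference itself differed between stages, by the record labels: 75 genes were called in cortex-labelled and 4 in brainstem-labelled libraries (edgeR quasi-likelihood, Benjamini-Hochberg). In cortex-labelled libraries the homeostatic list moved by a median of −1.08 and the disease-associated list by 2.65 on the log2 scale. By mouse number these medians were −0.41 and 0.54, and with an estimated correlation neither list passed (adjusted p = 0.218 each, against 0.0483 each by the record). Higher at end-stage were Abcg1 (2.36), Apoe (7.50), Bambi (4.81), Dgat2 (8.42), Dusp1 (3.18), Egr2 (5.03), Fabp5 (3.76) and Postn (4.79). Lower were Enpp5 (−10.25), Fcrls (−3.23), Ighm (−1.90), Jun (−1.75), Mmp28 (−10.41), Myo18b (−11.63), Ptger3 (−10.76) and Sema4b (−8.24). Enpp5, Mmp28, Myo18b and Ptger3 had 0 counts in both end-stage mutant libraries, so their fitted values have no measured size: the end-stage falls were at least 150-, 102-, 49.6- and 35.4-fold. In brainstem-labelled libraries Fcrls (−3.28) and Jun (−1.86) were lower. These differences take the 2-month genotype from the record, and the order of the running sample numbers argues for the other reading. Read by mouse number, 8 of the 16 named cortex-labelled genes and 1 of the 2 named brainstem-labelled genes remained called. Stage also differed in animals and in sex, since end-stage mice were all female and 3 of the 6 mice at 2 months were male. It differed in control genotype too. End-stage control M1375 carried the Braf allele without Cre, while every 2-month control was labelled with Cre and without the Braf allele.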

How the results depend on the processing

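Over 14 counts of called genes, 77 of 199 alternative values stayed within 1.5-fold and 122 moved further. Of 3396 alternative values for 255 named genes, 2904 were unchanged, called in both or in neither, 438 were weaker, 51 stronger and 3 reversed. Of 1400 for 131 lists, 963 were unchanged in the same sense, 398 were weaker, 7 stronger and 32 reversed. The cause of each move was not tested. With 2 or 3 mice per group, a change of 2-fold was mostly missed in data simulated with the spread of the record fit. Counts of few genes thus limit what can be said about small changes. Genotype comparisons are between mice, and mouse as a replicate block applied only to region and genotype by region.

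Counts are given in the order genotype in cortex-labelled then brainstem-labelled libraries at 2 months, the same at end-stage, genotype by region at 2 months then end-stage, genotype by stage in cortex-labelled then brainstem-labelled libraries, region in controls at 2 months then end-stage, and stage in controls in cortex-labelled then brainstem-labelled libraries. They were 1, 1, 171, 1, 0, 0, 75, 4, 10, 1, 3 and 2. With no low-count filter they were 149, 154, 1026, 436, 33, 162, 1011, 507, 734, 441, 473 and 248. With DESeq2 they were 5, 12, 694, 70, 4, 43, 506, 76, 267, 105, 41 and 32. With limma-voom they were 3, 1, 135, 1, 0, 1, 36, 2, 108, 11, 1 and 0. With only the compared groups they were 0, 1, 451, 4, 0, 0, 6, 2, 3, 0, 0 and 1. With the 2-month genotype by mouse number they were 904, 6, 666, 25, 4, 14, 44, 1, 24, 9, 0 and 0. The stricter low-count filter moved only region in controls at 2 months, to 22. Without the 4 mice whose genotype differs between readings, genotype by stage gave 2 and 1, region in controls at 2 months 0, and stage in controls 4 and 4, with 1 mouse per genotype left at 2 months.

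Without each mouse in turn, counts ranged from 0 to 1 and 0 to 1 for genotype at 2 months, 10 to 26 and 0 to 2 for genotype at end-stage, and stayed 0 for genotype by region. They ranged from 5 to 530 and 0 to 12 for genotype by stage, 1 to 2 and 0 to 2 for region in controls, and 0 to 3 and 0 to 1 for stage in controls. Values between these ends for genotype by stage in cortex-labelled libraries were 7, 16, 22, 28, 29, 37 and 352, and 18 and 22 for genotype at end-stage. By mouse number, genotype at 2 months gave 904 and 6 genes, with 1551 and 499 under no low-count filter, 1562 and 198 by DESeq2, 571 in cortex-labelled libraries with an added log2 threshold, and 11 in brainstem-labelled libraries by limma-voom and 2 with only the compared groups. Without each mouse these ranged from 462 to 677, with 585 between, and from 0 to 11, with 1, 2, 7 and 9 between.

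With mouse as a replicate block, which uses the pairing of regions within a mouse, genotype by region gave 0 at 2 months and 5 at end-stage, and region in controls gave 274 at 2 months and 30 at end-stage. The block ended the camera calls of astrocytes (0.295) and border-associated macrophages (0.115) in controls at 2 months, of brainstem tissue identity (0.133) in end-stage controls, and of oligodendrocyte precursors (0.0546) in genotype by region at end-stage. It changed no other list call.

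Reading the 2-month genotype by mouse number turned the direction that camera gave to lists called under at least 1 reading, shown here with the adjusted camera p by mouse number. This reading of lists was added after the data were seen. Where that p is 0.05 or more, the call by the record was lost and no direction is held by mouse number. The median kept its sign for border-associated macrophages in genotype brainstem 2 months (−1.57 by the record and −0.42 by mouse number) and for homeostatic microglia in stage in controls cortex (0.23 and 0.01). For genotype cortex 2 months these were homeostatic microglia (1.91e-06), disease-associated microglia (3.56e-08), ERK pathway output (0.00915), interferon response (6.33e-43), cytokines and chemokines (1.18e-12), cell cycle (2.81e-29) and antigen presentation (4.18e-09). For genotype brainstem 2 months these were ERK pathway output (6.22e-09), interferon response (1.21e-28), cytokines and chemokines (4.87e-09), cell cycle (6.15e-11), senescence-linked (0.0921), border-associated macrophages (0.906) and B and plasma cells (0.00359). For genotype by region 2 months these were lysosome (2.42e-07) and border-associated macrophages (0.0351). For genotype by stage cortex these were interferon response (4.35e-16), cytokines and chemokines (0.00202), antigen presentation (0.00202), lysosome (0.400) and monocytes (0.572). For genotype by stage brainstem these were ERK pathway output (0.0617), cytokines and chemokines (0.182) and B and plasma cells (0.751). For region in controls 2 months these were disease-associated microglia (0.679) and border-associated macrophages (0.525). For stage in controls cortex these were homeostatic microglia (0.631), interferon response (6.66e-07), cytokines and chemokines (0.00384) and cell cycle (0.0209), and for stage in controls brainstem interferon response (0.333). Itgax (2.67), P2ry12 (−1.10) and Sall1 (−0.59) reversed in genotype cortex 2 months. T and NK cells reversed in genotype cortex end-stage with no low-count filter (0.784).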

Other observations

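The tests of the 2-month reading and of the region label, the border macrophage test, the Apoe test, the splits by the record and the look at single astrocyte genes were chosen after the result was seen. The Cre-free mouse test and the splits of the mouse-number reading and of region were fixed before.

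Genes lower in cortex-labelled mutants at end-stage recurred at 2 months when genotype was read by mouse number, although the 2 comparisons share no library. Of 108 genes lower at end-stage and 300 lower at 2 months, 25 were shared, where 1.95 would be shared by independent draws from 16595 genes. Of 63 and 604 higher genes 4 were shared, where 2.29 would be. With both comparisons in the mouse-number model, 133 of 304 and 604 higher genes were shared (11.1 expected) and 120 of 362 and 300 lower genes (6.54 expected). In each case 0 genes moved in opposite directions. The 2 comparisons share 1 model and its spread, so the expected numbers are a guide only. Sema4b and Myo18b were among the lower genes of both. In contrast, cell-cycle genes were higher at 2 months under that reading (median 3.70) and not at end-stage (−0.19).

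Hypothesis: the 4 mice carry the genotype of their column number. The running sample numbers in the column names argue for it, since they put the columns' mouse numbers in the order of the titles. A score of 100 higher and 100 lower genes of the end-stage cortex-labelled response ranked this call 1 of 20 in cortex-labelled and 2 of 20 in brainstem-labelled libraries, and the record's call 17 and 20. By mouse number Etv4 did not overlap between genotypes in cortex-labelled (5.93 to 7.18 against 0 to 2.51 CPM) or brainstem-labelled libraries (1.76 to 3.73 against 0 to 1.24 CPM). By the record it overlapped in both, and its test passed under neither reading. Camera placed ERK output in brainstem-labelled libraries lower by the record (median −0.43) and higher by mouse number (0.68). Neither call held with an estimated correlation. An effect of unequal sexes is argued against, because a split by sex called 6 genes in cortex-labelled libraries where the mouse-number split called 904. Cells of another type may add to it and stay open, as the border macrophage list had a median of −1.95 while monocyte genes rose. Prkd1 runs the other way, being present at 2 months in record controls alone. It had 0 counts in every end-stage library, controls included, so it does not mark control genotype as such. The records may also hold a difference between the mice that neither reading names.

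Hypothesis: brainstem transcripts in cortex-labelled libraries could come from cortex and brainstem labels exchanged. Exchange would also put cortex transcripts in brainstem-labelled libraries, and these were higher there in 6 of 10 mice, which leaves exchange open. Deeper cortex-labelled libraries are argued against, since that library was the deeper in 4 of 10 mice. More carry-over RNA of every neural cell stays open, with neuron transcripts higher in cortex-labelled libraries in 6 of 10 mice. The astrocyte sum was higher in the brainstem-labelled library in 10 of 10 mice (645 against 862 CPM, exact p = 0.00195) and the oligodendrocyte sum in the cortex-labelled one in 9 of 10 (237 against 202 CPM, exact p = 0.00977, 0.0195 adjusted), but Slc1a3 made up most of the astrocyte sum (586 against 785 CPM), while Gfap and Aldh1l1 were higher in the cortex-labelled library in 10 of 10.

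Hypothesis: the end-stage difference in cortex-labelled libraries is a change within microglia toward lipid loading and efflux, with Apoe, Lpl, Abca1 and Abcg1. Lipid loading and efflux themselves were not tested, and the camera call of the lipid list did not hold with an estimated correlation. Abcg1 was also higher in brainstem-labelled than in cortex-labelled record controls at both stages, where Apoe was not. Its level alone therefore does not mark such a state. Apoe took up to 9.47% of the counts, which can lower other genes by at most 0.143 on the log2 scale. The smallest difference of the other called genes was 0.76, more than this share can give. Genes were called by their p-value, and differences near 0.143 could hardly pass. The comparison bounds the size of the effect and is no independent test. The Cre-free control mouse is argued against for the direction of the disease-associated and homeostatic lists, which passed camera at the preset correlation without it (the higher adjusted p was 2.61e-10), although with all mice both stood at 0.0528 with an estimated correlation. Single genes depended on each of the 4 mice, as the count of 171 fell to 10 without that mouse and to 18 to 26 without another, and Apoe lost its call without either control (0.0896 and 0.0542). Border macrophages or monocytes in the mutant libraries may contribute and stay open, as the monocyte list had a median of 0.21.

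Splits of the 6 mice at 2 months into 3 and 3 number 10, too few for a share under 0.05. By the record, 4 of 10 splits called at least as many genes in cortex-labelled libraries (real 1, highest other 904), 5 in brainstem-labelled libraries (1, highest other 7) and 10 for genotype by region (0, highest other 4). By mouse number, 1 split in cortex-labelled libraries (904, highest other 6) and 2 in brainstem-labelled libraries (6, highest other 7) did. The split that called 904 genes was the mouse-number split. The structure it points to follows a number in the descriptions of the same records, not the genotype those records give. For region in controls at 2 months the splits are of 6 libraries from 3 mice, again too few (real 10, highest other 0, 1 of 10 as large). Only the real split and 3 others part all 3 pairs of libraries, and the other 6 part 2.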
